A study of Mus musculus with 24 samples.

How the data were processed

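The series measured RNA in liver and kidney of C57BL/6 mice in 4 arms: untreated control, CBLB502 (a flagellin-derived agonist of the receptor TLR5), cisplatin, and CBLB502 followed by cisplatin, called the combination here. Cisplatin was injected into the peritoneum at 20 mg/kg, CBLB502 was given at 0.2 mg/kg 30 min before it, and tissue was taken at 72 h, per the labels and the series design text. The labels give no time, clock time or dose for the controls. Each tissue and arm has 3 libraries, which makes 8 groups and 24 libraries. Total RNA was extracted with Trizol and libraries followed a standard Illumina preparation, per the labels' protocols. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part.

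The authors deposited a table of 33272 Ensembl gene IDs with symbols and coordinates, with columns of raw counts and of FPKM per library, per the file headers. The submitters' processing notes name cutadapt 1.9 and FastQC. The aligner, the counting program, the strand setting, the genome build and the annotation were not given in the sources used here, nor was the transcript length behind the FPKM values. Coordinates were compared with the GENCODE vM21 annotation of the mouse build GRCm38: 99.65% of the IDs were in it, all 33156 of those on the same chromosome, and 99.7% of them shared a start or an end. The table holds 66 symbols that stand on several IDs, and such genes, near-identical copies and overlapping genes are uncertain because reads can be split between them.

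Columns were tied to groups by the letters in their names (K or L for the tissue; NC control, NC502 CBLB502, C cisplatin, C502 combination). Control and liver columns are numbered 1 to 3 and match the replicate numbers of the labels. The treated kidney columns are numbered 4 to 6, which the labels do not use, so these columns were tied to a group and not to a single sample. Libraries are named by column number. Of the FPKM columns, 15 match a single sample and were used, and 9 columns of treated kidney FPKM were not used. FPKM of kidney libraries were therefore computed from counts, library totals and the gene length that the deposited FPKM of the other libraries imply. For genes at 0 in all of those, the GENCODE exon length was scaled to them. These computed values set the FPKM level for naming genes, the FPKM filter and the FPKM test in kidney.

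Gene counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr, TMM scaling (trimmed mean of M-values), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 libraries of a tissue were fitted together, which left 17931 genes in liver and 20341 in kidney, and the difference between tissues came from a single fit of all 24 libraries over 21570 genes. The design had been written before the data were examined, together with the alternatives, the gene lists and the rule for naming genes. It assumed FPKM with limma and named this edgeR test as the choice for a table with whole-number counts. Comparisons planned there were each treated arm against control, the combination against cisplatin, the interaction (combination minus CBLB502, minus cisplatin plus control) and the tissue differences. The comparisons of the combination and of cisplatin with CBLB502 were added after the data were seen.

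Levels are counts per M (CPM) on TMM-scaled library sizes and need not sum to the same total in each library. Folds are ratios of group mean CPM. Log2 fold changes with SE come from the fit, and log2 CPM have a prior count of 2. Where a gene had no count in a whole group, the fold is a bound against 3 counts over that group. Such bounds cover counting error only.

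Gene lists, 32 in number, covered pathways and cell types, and 599 of their 603 genes were in the table. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was the alternative. Named genes were the 6 highest and 6 lowest changes per comparison (5 each way for the interaction and the tissue differences) among called genes whose groups did not overlap, with at least 5 FPKM in the higher group and leaving out predicted models. Up to 3 called members of each list were added, and Cdkn1a, Mdm2, Havcr1, Lcn2, Slc22a2, Saa1, Tlr5, Alb and Cyp7a1 were named whatever their result. Some genes that the rule names are not reported here.

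The share of the cisplatin effect left in the combination was computed per tissue and direction with 1 control and 1 cisplatin library held out. Genes were called without them, and the mean change of the combination from the held-out control was divided by that of the held-out cisplatin library, over 9 choices.

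Depth per library ran from 40.58 to 77.54 M counts (M for mega) in liver and from 52.85 to 77.1 M in kidney. No pair of libraries within a group held identical counts, and chi-square per degree of freedom between them ran from 29.24 to 2132 over 24 pairs. The code was tested on simulated counts for the real genes and library sizes with 200 changed genes. At the 4-fold level it recovered 31.2% of changed genes for liver cisplatin against control, 41.2% for the combination against cisplatin in each tissue, and 56.2% for kidney cisplatin against control. At the 2-fold level these were 0%, 2.5% in liver and 8.75% in kidney, and 8.75%. It called 0 of 20 unchanged lists and gave a held-out ratio of 0.527 in liver and 0.525 in kidney for a true 0.5.

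Alternatives were median-of-ratios scaling, quantile normalization, no filter, a filter of at least 5 FPKM in 3 libraries, only the groups of a contrast in the fit, library weights by limma-voom, the replicate number as a block, and each library left out in turn. Added after the data were seen were limma-voom without weights, DESeq2 1.42.0, limma on log2(FPKM + 1), fits without control libraries, fits without mitochondrial genes and their chromosome 1 copies, and CBLB502 libraries in place of control in the held-out ratio. Tables were joined and plotted with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.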

Results

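RNA was sequenced from liver and kidney of C57BL/6 mice to ask whether CBLB502, an agonist of the flagellin receptor TLR5, alters the response of these organs to the platinum drug cisplatin. Each tissue had 4 groups of 3 libraries: untreated control, CBLB502, cisplatin, and the combination of CBLB502 given before cisplatin. Levels below are mean counts per M (M for mega; CPM) ± SD with n = 3 libraries per group, and log2 fold changes are given ± SE. An adjusted p is from edgeR unless another test is named.

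The control libraries of both tissues differed from all treated libraries in their mitochondrial transcripts. Mitochondrial genes took 71.2% ± 1.64 (SD, n = 3) of counts in control liver and 64.7% ± 4.14 in control kidney. The treated groups of liver had means of 6.97% ± 0.21 with CBLB502, 3.74% ± 1.71 with cisplatin and 4.84% ± 0.433 with the combination. Those of kidney had 13.6% ± 0.524, 8.12% ± 2.02 and 7.6% ± 0.177. A further 19.79% to 20.93% of control liver counts and 20.13% to 21.89% of control kidney counts fell on 7 pseudogenes on chromosome 1 (24611535 to 24616197), which are nuclear copies of mitochondrial sequence. This left 2.819 to 4.649 M counts for all other genes in control liver, against 48.6 to 74.5 M in treated liver, and 5.054 to 10.14 M against 44 to 68.83 M in kidney. Every comparison with control also compares these kinds of library.

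**Figure D1:**
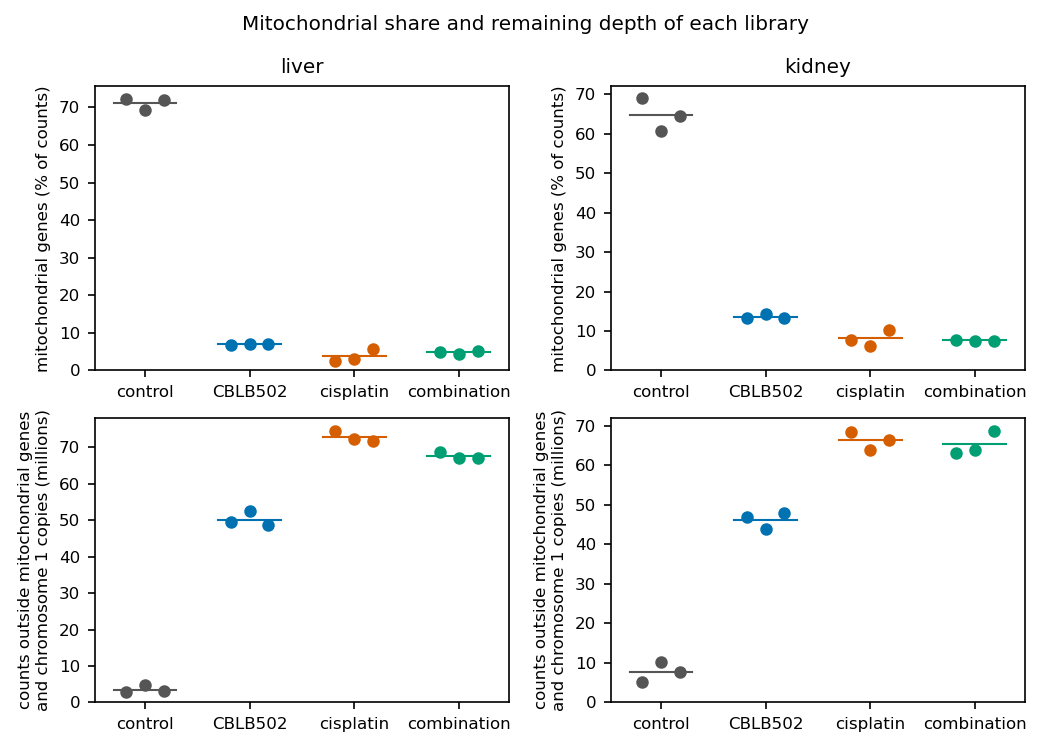
Percent of counts on mitochondrial genes (top) and M (mega) counts outside mitochondrial genes and their chromosome 1 copies (bottom) in liver and kidney; each point is a library and each line a group mean.

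On the first principal component, which held 37.6% of the variance in liver and 42.1% in kidney, the control libraries lay apart from all treated libraries. Liver cisplatin library 3 was 1.6 (log2 units) from the other cisplatin libraries and at least 1.13 from any pair of combination libraries. For libraries 1 and 2 these were 1.16 and 1.49, and 0.997 and 1.36. Kidney cisplatin library 6 was at 1.41 and 0.848, library 4 at 1.04 and 1.21 and library 5 at 1 and 1.17. Own-group values of the others include library 3 or 6.

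**Figure D2:**
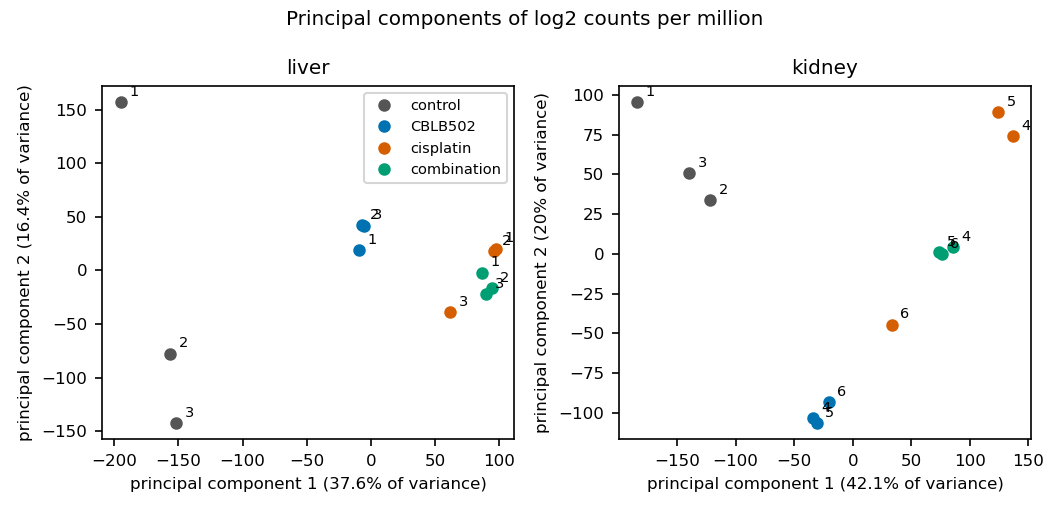
Libraries of liver and kidney on the first and second principal components of log2 CPM, coloured by group and numbered by library.

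In liver, cisplatin against control asked what the drug alone did at 72 h. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53-induced inhibitor of the cell cycle, was 59-fold higher, at 281.5 ± 163 CPM against 4.768 ± 1.57 (log2 fold change 5.89 ± 0.531, adjusted p = 1.29e-05). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32387797), which binds bacterial siderophores and is secreted in injury, rose 644-fold to 3714 ± 3330 CPM (9.33 ± 1.41, adjusted p = 0.000327). The acute-phase gene Saa1 (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980) rose 592-fold to 11870 ± 12700 CPM (9.21 ± 1.57, adjusted p = 0.000697). Haemoglobin transcripts fell, with Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103827928) 442-fold lower at 0.2893 ± 0.166 CPM against 127.9 ± 78.1 (-8.79 ± 0.736, adjusted p = 9.03e-06).

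Of 24 measured p53 target genes, 19 rose in liver, and 19 when adjusted over the list alone (median log2 fold change 2.22, or 2.21 with a gene absent from the controls at its bound; camera adjusted p = 1.2e-06, and adjusted p = 0.166 with an estimated correlation). The antiproliferative gene Btg2 rose 52.1-fold (5.70 ± 1.07, adjusted p = 0.00134), while Mdm2, the ubiquitin ligase of p53, rose 1.74-fold (0.80 ± 0.282, adjusted p = 0.039). Acute-phase genes rose in 24 of 26 cases (25 adjusted over the list alone; median 4.32; camera adjusted p = 1.25e-09, and adjusted p = 0.301 with an estimated correlation), among them the fibrinogen gene Fga, 26-fold higher (4.70 ± 0.63, adjusted p = 0.000144). The metal-binding Mt1 and Mt2 rose 153-fold and 139-fold (adjusted p = 5.08e-05 and 0.000262), and the insulin-like growth factor binding protein Igfbp1 rose 72.6-fold (6.18 ± 1.09, adjusted p = 0.00086). These 3 belong to genes of fasting and glucocorticoid response, of which 15 of 21 rose and 1 fell, with the same counts adjusted over the list alone (median 2.15; camera adjusted p = 6.57e-06, and adjusted p = 0.166 with an estimated correlation). Of 26 hepatocyte function genes, 19 rose (20 adjusted over the list alone; median 1.73; camera adjusted p = 1.93e-06, and adjusted p = 0.167 with an estimated correlation), including Alb, which encodes albumin, at 4.1-fold (2.04 ± 0.362, adjusted p = 0.000913).

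Erythroid, lymphocyte, macrophage and stromal transcripts fell in liver, while neutrophil genes had 1 of 9 higher and 1 lower (0 and 1 adjusted over the list alone; median 2.11; camera adjusted p = 0.895). All 5 erythroid genes fell (5 adjusted over the list alone; median -9.17; camera adjusted p = 1.88e-06, and adjusted p = 0.166 with an estimated correlation), with Hba-a2, Hba-a1 and Hbb-bt 795-fold, 703-fold and 569-fold lower (adjusted p = 3.07e-05, 8.17e-05 and 4.18e-05). Among 21 lymphocyte genes 17 fell (17 adjusted over the list alone; median -5.66, or -5.48 with genes absent from a group at their bound; camera adjusted p = 5.43e-09, and adjusted p = 0.167 with an estimated correlation). The listed T cell gene Cd8a fell at least 560-fold and the immunoglobulin gene Igkc 264-fold (adjusted p = 0.000132 and 1.86e-05). Igkc overlaps a predicted gene and is uncertain. Stromal genes fell in 14 of 15 cases and 1 rose, also adjusted over the list alone (median -3.31; camera adjusted p = 1e-05, and adjusted p = 0.301 with an estimated correlation), with the smooth muscle actin gene Acta2 122-fold lower (adjusted p = 0.000659). Macrophage genes fell in 11 of 20 cases and 1 rose, also adjusted over the list alone (median -1.92; camera adjusted p = 0.0011, and adjusted p = 0.301 with an estimated correlation). Vsig4, a complement receptor of Kupffer cells, fell 14.8-fold (adjusted p = 0.000451). The mitochondrial transfer RNA mt-Td fell with the mitochondrial share itself (-7.88 ± 0.811, adjusted p = 2.7e-05).

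Several genes without a count in control liver were present after cisplatin. Chil3, a chitinase-like gene of macrophages, was at least 94.4-fold higher (adjusted p = 0.00215), and the trefoil factor gene Tff3 at least 266-fold (adjusted p = 0.00664). The sulfotransferase gene Sult2a7 was at least 113-fold higher (adjusted p = 0.0161). Ptp4a1, a tyrosine phosphatase gene, was at least 2240-fold higher (adjusted p = 4.69e-07), but its symbol stands on several IDs and it is uncertain. Not called were Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.81 ± 1.52, adjusted p = 0.354), and Tlr5, the receptor of CBLB502 (-0.63 ± 0.951, adjusted p = 0.615). Nor were the kidney genes Havcr1 and Slc22a2 (adjusted p = 0.699 and 0.713).

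Over all tested liver genes, 7727 of 17931 were called, 4588 higher and 3139 lower, and 9096 had an unadjusted p under 0.05. With median-of-ratios scaling 3732 were higher and 3795 lower, because that scaling moved the median of all genes from 0.09 to -0.14 on the log2 scale. On log2(FPKM + 1) 8858 were higher and 125 lower, with a median of 1.43. The Mdm2 call ended without control 1, 2 or 3 (adjusted p = 0.114, 0.0655 and 0.052) and without cisplatin 1 or 3 (0.111 and 0.0824). Cyp7a1 fell by 3.69 without cisplatin 3 (adjusted p = 0.00984). Under limma-voom Tff3 had an adjusted p of 0.436, Sult2a7 0.312 and Chil3 0.192.

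**Figure D3:**
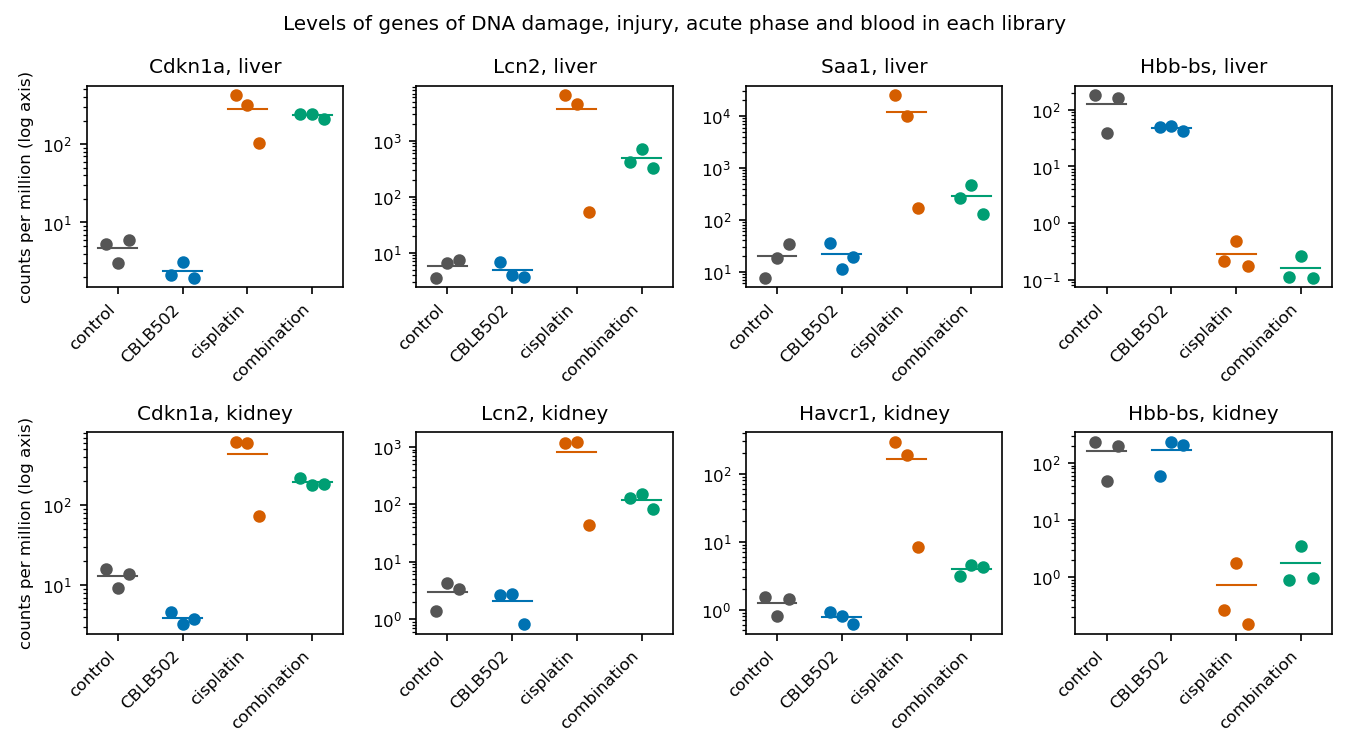
Levels in counts per M (log axis) of Cdkn1a, Lcn2, Saa1 and Hbb-bs in liver and of Cdkn1a, Lcn2, Havcr1 and Hbb-bs in kidney; each point is a library and each line a group mean.

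CBLB502 against control in liver asked what the agonist did alone. The PPAR alpha target Cyp4a14, a fatty acid hydroxylase, rose 62.9-fold to 161.6 ± 53.5 CPM from 2.568 ± 0.66 (5.97 ± 1.12, adjusted p = 0.00247). The fatty acid desaturase gene Fads2 rose 11.1-fold (3.47 ± 0.417, adjusted p = 0.000174). Mitochondrial transcripts fell with the mitochondrial share, with mt-Cytb, a subunit of complex III (ENSMUSG00000064370, chromosome MT, 14145 to 15288), 112-fold lower at 3973 ± 230 CPM against 444800 ± 69800 (-6.81 ± 0.389, adjusted p = 1.56e-06). Saa1 was at 22.17 ± 13.1 CPM and 20.05 ± 13.2 CPM in control (0.15 ± 1.11, adjusted p = 0.935), and Lcn2 at 4.881 ± 1.73 and 5.768 ± 1.99 CPM (-0.24 ± 1.01, adjusted p = 0.878).

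Metabolic lists rose in CBLB502 liver by the preset test. Of 25 fatty acid oxidation genes 15 rose (18 adjusted over the list alone; median 1.54). Of 21 cholesterol synthesis genes 13 rose (15 adjusted over the list alone; median 1.60), including Cyp51, 9.7-fold higher (adjusted p = 0.00138). Both lists had a camera adjusted p of 6e-06, and both and the next 4 lists had adjusted p = 0.863 with an estimated correlation. Hepatocyte function genes rose in 14 of 26 cases (16 adjusted over the list alone; median 0.99; camera adjusted p = 0.000101), with Alb 3.17-fold higher (1.66 ± 0.357, adjusted p = 0.00521) and the urea cycle gene Cps1 6.69-fold higher (2.74, adjusted p = 0.00105). Xenobiotic cytochrome P450 genes rose in 10 of 22 cases (12 adjusted over the list alone; median 1.91, or 1.92 with a gene absent from a group at its bound; camera adjusted p = 0.00312), with Cyp3a11 11.3-fold higher (3.49 ± 0.892, adjusted p = 0.0128). Fatty acid synthesis genes rose in 10 of 18 cases (12 rose and 1 fell adjusted over the list alone; median 1.14; camera adjusted p = 0.00381). Lymphocyte genes fell in 5 of 21 cases (3 adjusted over the list alone; median -1.44; camera adjusted p = 0.00381), with Cd8a 22.4-fold lower (-4.48, adjusted p = 0.00315). Acute-phase genes had 5 members higher and 1 lower, also adjusted over the list alone (median 0.34, camera adjusted p = 0.363), and NF-kB and chemokine genes 0 higher and 1 lower, or 0 lower adjusted over the list alone (median -0.31; camera adjusted p = 0.254).

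Clock genes moved both ways in CBLB502 liver, 6 of 16 higher and 4 lower (median 1.07, cisplatin 1.09, combination 1.26; camera adjusted p = 0.281). Control clock times were not given. The output gene Dbp rose 79.9-fold (6.40 ± 1.48, adjusted p = 0.0076) and the repressor gene Nr1d1 14.8-fold (3.88 ± 0.421, adjusted p = 0.000105), while the activator gene Npas2 fell 69.2-fold (-6.08, adjusted p = 0.00678). Also higher were the retinol dehydrogenase gene Rdh9, 52.2-fold (adjusted p = 0.000197), and the glucuronosyltransferase genes Ugt1a5 and Ugt1a6a, 26.1-fold and 18.8-fold (adjusted p = 0.00197 and 0.000231). These overlap neighbours and are uncertain, as is Ptp4a1, at least 370-fold higher (adjusted p = 2.14e-06). Igfbp1 fell 10.7-fold (-3.42 ± 0.96, adjusted p = 0.0202). Other mitochondrial genes fell alike: mt-Nd4 108-fold, mt-Nd4l 116-fold, mt-Nd2 93.1-fold, mt-Co2 86-fold and mt-Td 162-fold, with adjusted p from 6.93e-07 to 9.6e-05. Not called were Cdkn1a (-0.98 ± 0.446, adjusted p = 0.126), Mdm2 (-0.27, adjusted p = 0.51), Tlr5 (adjusted p = 0.145) and Cyp7a1 (3.27 ± 1.6, adjusted p = 0.153).

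In total 4984 of 17931 liver genes were called for CBLB502, 3284 higher and 1700 lower, with 7027 at an unadjusted p under 0.05. Median-of-ratios scaling gave 2341 higher and 2335 lower and moved the median of all genes from 0.14 to -0.10, and on log2(FPKM + 1) 9755 were higher and 63 lower at a median of 1.80. The Cyp3a11 call ended without control 3 (adjusted p = 0.0504), the Igfbp1 call without control 3 (0.0601) or CBLB502 1, 2 or 3 (0.0757, 0.07 and 0.0612), Tlr5 was called without control 2 (0.04), and mt-Cytb was not called after quantile normalization (0.0754).

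The combination against cisplatin in liver asked whether CBLB502 changed the response to the drug. Saa1 was 41.4-fold lower at 287.1 ± 169 CPM against 11870 ± 12700 (-5.37 ± 1.32, adjusted p = 0.0489). The calprotectin genes S100a8 and S100a9 of neutrophils were 185-fold and 85.7-fold lower (-7.49 ± 1.39 and -6.41 ± 1.21, adjusted p = 0.0193 and 0.02). Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407709), the desaturase that makes oleate, was 22.5-fold lower at 16.51 ± 5.36 CPM (-4.49 ± 0.656, adjusted p = 0.00903). Bhmt, which remethylates homocysteine, was 6.43-fold higher at 10390 ± 1170 CPM against 1617 ± 1710 (2.68 ± 0.641, adjusted p = 0.0448). Cdkn1a was at 233.2 ± 19.5 CPM in the combination and 281.5 ± 163 CPM with cisplatin (-0.27 ± 0.424, adjusted p = 0.789).

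Of 26 acute-phase genes 8 were lower (18 lower and 1 higher adjusted over the list alone; median -2.12; camera adjusted p = 9.54e-08, and adjusted p = 0.554 with an estimated correlation). Also lower was Serpina3f, 83.7-fold (adjusted p = 0.0193). Macrophage genes were lower in 5 of 20 cases (8 adjusted over the list alone; median -1.42; camera adjusted p = 3.29e-07, and adjusted p = 0.199 with an estimated correlation), including the endotoxin co-receptor Cd14, 102-fold lower (adjusted p = 0.0331). Neutrophil genes were lower in 3 of 9 cases (8 adjusted over the list alone; median -6.41; camera adjusted p = 7.2e-06, and adjusted p = 0.344 with an estimated correlation), with the protease gene Mmp9 at least 127-fold lower (adjusted p = 0.028). NF-kB and chemokine genes were lower in 2 of 25 cases (5 adjusted over the list alone; median -1.19; camera adjusted p = 0.000161, and adjusted p = 0.344 with an estimated correlation). Among them was the NF-kB subunit gene Relb, 18.1-fold lower (adjusted p = 0.042). Regulated cell death genes were lower in 3 of 21 cases (5 adjusted over the list alone; median -0.84; camera adjusted p = 0.000762, and adjusted p = 0.199 with an estimated correlation). Of these, the cytokine receptor gene Tnfrsf12a was 7.24-fold lower (adjusted p = 0.0375). The apoptosis gene Bax, from the p53 list, was 1.91-fold lower (-0.94 ± 0.161, adjusted p = 0.0143). Of 24 p53 target genes 1 was lower, also adjusted over the list alone (median -0.40, camera adjusted p = 0.402).

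Also lower in the combination were Hmox1, the haem-degrading oxygenase, 11-fold (-3.47 ± 0.628, adjusted p = 0.0177), and Il1rn, the interleukin-1 receptor antagonist, 70.3-fold (adjusted p = 0.0404). Higher were the clock repressor gene Ciart, 6.04-fold (2.59 ± 0.391, adjusted p = 0.00984), the fatty acid hydroxylase genes Cyp4a12b and Cyp4a12a, 9.25-fold and 5.32-fold (adjusted p = 0.0263 and 0.0425), and Cps1, 3.37-fold (adjusted p = 0.0481). The carbonic anhydrase gene Car14 and Spata2l, a paralog of a TNF receptor adaptor gene, were 5.09-fold and 6.55-fold higher (adjusted p = 0.0201 and 0.0333). The small RNA genes Rn7s1, Rn7s2 and Rpph1 were lower as well (adjusted p = 0.0477, 0.0461 and 0.0234). In cisplatin library 3 they had 292, 294.4 and 22.66 CPM, and at most 2.389, 2.548 and 1.65 in libraries 1 and 2. Not called were Lcn2 (-2.94 ± 1.06, adjusted p = 0.138), Mdm2 (0.97 ± 0.278, adjusted p = 0.0763), Alb (adjusted p = 0.904), Tlr5 (1.62, adjusted p = 0.34) and Cyp7a1 (1.71 ± 1.49, adjusted p = 0.57).

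Saa1 was at 25320, 10130 and 171.1 CPM in cisplatin libraries 1, 2 and 3 and at 131.8 to 467.6 in the combination, Lcn2 at 6566, 4522 and 53.42 against 325.5 to 717.2, and Cdkn1a at 422.8, 318.9 and 102.8 against 210.7 to 245.8. In total 640 genes were called, 178 higher and 462 lower, and 3790 had an unadjusted p under 0.05; DESeq2 called 863 higher and 1677 lower. The majority turned with limma-voom (1061 higher and 882 lower, or 3979 and 3478 with library weights) and on log2(FPKM + 1) (2175 and 629). Without cisplatin 3 the counts were 2365 higher and 1979 lower, and Lcn2, Mdm2, Cyp7a1 and Tlr5 were then called (adjusted p = 0.000172, 0.0156, 0.00109 and 0.0441). Without cisplatin 1 or 2 it was 175 or 161 and 9 or 8 of the 22 called genes named here kept their call; without combination 1, 2 or 3 it was 32, 7 or 21 and 0 of the 22 did.

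The combination against CBLB502 in liver, a comparison without control libraries, asked what cisplatin did in mice that had received the agonist. Cdkn1a rose 97.1-fold from 2.403 ± 0.619 CPM (6.60 ± 0.543, adjusted p = 0.000176), and Mdm2 and the p53 target Phlda3 rose 4.09-fold and 30.2-fold (2.03 ± 0.287 and 4.92 ± 0.593, adjusted p = 0.00196 and 0.000834). Hbb-bs fell 296-fold from 47.74 ± 4.26 to 0.1611 ± 0.0906 CPM (-8.20 ± 0.725, adjusted p = 0.000241). Scd1 fell 148-fold from 2449 ± 1270 CPM (-7.21 ± 0.744, adjusted p = 0.000441). Lcn2 rose 99.2-fold (6.63 ± 1.26, adjusted p = 0.00984), and Saa1 was 12.9-fold higher without passing the test (3.70 ± 1.22, adjusted p = 0.0999).

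In this comparison 8 lists kept their call with an estimated correlation. Of 24 p53 target genes 17 rose (18 adjusted over the list alone; median 2.59; camera adjusted p = 1.78e-28, and adjusted p = 0.00159 with an estimated correlation). Fasting and glucocorticoid response genes rose in 14 of 21 cases (17 adjusted over the list alone; median 2.03; camera adjusted p = 6.57e-27, and 0.00159), with Igfbp1, Mt2 and Mt1 115-fold, 335-fold and 91.7-fold higher (adjusted p = 0.00457, 0.00125 and 0.000852). All 5 erythroid genes fell (5 adjusted over the list alone; median -8.18; camera adjusted p = 6.6e-15, and 0.00399), Hbb-bt 498-fold, Hba-a2 296-fold and Hba-a1 142-fold (adjusted p = 0.000658, 0.000738 and 0.00255). Macrophage genes fell in 14 of 20 cases (16 adjusted over the list alone; median -3.41; camera adjusted p = 3.69e-24, and 0.00399), with the lysozyme gene Lyz2 17.6-fold lower (-4.14 ± 0.544, adjusted p = 0.00127). Lymphocyte genes fell in 14 of 21 (19 adjusted over the list alone; median -7.07, or -4.95 with genes absent from a group at their bound; camera adjusted p = 2.14e-18, and 0.0403). Endothelial genes fell in 10 of 15 (12 adjusted over the list alone; median -3.27; camera adjusted p = 1.1e-14, and 0.0403), with the fenestration gene Plvap 18.3-fold lower (adjusted p = 0.00057). Stromal genes fell in 9 of 15 (10 fell and 1 rose adjusted over the list alone; median -2.54; camera adjusted p = 7.52e-13, and 0.0403), with Reln, made by stellate cells, 21.8-fold lower (adjusted p = 0.000951). Cell cycle genes fell in 3 of 24 (5 adjusted over the list alone; median -1.47; camera adjusted p = 2.15e-05, and 0.0146). Acute-phase genes rose in 9 of 26 (12 adjusted over the list alone; median 1.71; camera adjusted p = 7.57e-11, and adjusted p = 0.178 with an estimated correlation).

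Another gene of this comparison was Sult1e1, an oestrogen sulfotransferase, 299-fold higher (8.22 ± 1.46, adjusted p = 0.00716). The nuclease gene Dnase1l3 was 58.7-fold lower (adjusted p = 0.0381) and the chemokine gene Cxcl10 15.6-fold lower (-3.96, adjusted p = 0.0067). Alb was not called (adjusted p = 0.809). In total 1209 genes were called, 516 higher and 693 lower, and 3545 had an unadjusted p under 0.05; DESeq2 called 2604 and limma-voom 2805. Without CBLB502 1, 2 or 3 the count was 478, 526 or 599, and without combination 1, 2 or 3 it was 549, 514 or 543. The Lcn2 call ended without CBLB502 2 or 3 (adjusted p = 0.0566 and 0.0531), and the Dnase1l3 call ended without any 1 of the 6 libraries (0.0661 to 0.124).

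Across genes, the cisplatin change measured against control and the one measured in the combination against CBLB502, which share no library, had a Pearson r of 0.421 and a Spearman rho of 0.405 in liver (covariance 1.8); genes are not independent replicates. Both comparisons called 337 genes higher, where independent lists would share 132, and 477 lower, where they would share 121.3, and 56 genes went opposite ways. The combination against control called 7203 genes, 4264 higher and 2939 lower (8882 at an unadjusted p under 0.05), or 3109 higher and 3703 lower with median-of-ratios scaling. Of the liver cisplatin effect, a ratio of 0.924 (range 0.846 to 1.05 over 9 choices) remained in the combination for genes that rose and 0.932 (0.79 to 1.17) for genes that fell. By held-out cisplatin library 1, 2 and 3, the ratio for genes that rose was 0.897, 0.852 and 1.02, and for genes that fell 0.82, 0.84 and 1.14. Control libraries enter both terms of these ratios; with CBLB502 libraries in their place the ratios were 0.57, 0.563 and 0.97, and 0.844, 0.915 and 1.55.

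The liver interaction asked whether the cisplatin change differed with and without CBLB502. Mitochondrial genes, low in every treated group, had the most positive values: mt-Td (7.74 ± 1.03), mt-Nd4l (7.28 ± 0.62), mt-Nd4 (7.14 ± 0.564), mt-Cytb (7.08 ± 0.471) and mt-Nd2 (6.67 ± 0.555), with adjusted p from 8.14e-06 to 0.00064. The leptin receptor gene Lepr (-9.49 ± 2.09, adjusted p = 0.00798), the stress gene Ier3 (-7.47 ± 2.02, adjusted p = 0.0216) and Serpina3f (-7.43 ± 1.56, adjusted p = 0.00628) had a smaller cisplatin increase with CBLB502. Acute-phase genes were lower in 13 of 26 cases (17 adjusted over the list alone; median -3.01; camera adjusted p = 0.000535). Cholesterol synthesis genes were lower in 8 of 21 (9 adjusted over the list alone; median -1.89; camera adjusted p = 0.00069). Both had adjusted p = 0.872 with an estimated correlation. In total 3885 genes were called, 1281 higher and 2604 lower (6123 at an unadjusted p under 0.05), or 1599 higher and 2061 lower with median-of-ratios scaling, which moved the median of all genes from -0.23 to -0.02, or 86 and 8696 on log2(FPKM + 1). The Ier3 call ended without control 2 or 3 (0.058 and 0.0508) and without combination 2 or 3 (0.0523 and 0.0542). Under limma-voom Lepr had an adjusted p of 0.469, Ier3 0.619 and Serpina3f 0.322, and mt-Cytb 0.0585 after quantile normalization.

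In kidney, cisplatin against control showed injury, p53 and acute-phase genes higher. Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), which encodes the tubular injury marker KIM-1, rose 128-fold from 1.266 ± 0.387 to 162.2 ± 144 CPM (7.04 ± 1.03, adjusted p = 0.000362). The injury genes Lcn2 and Krt20 rose 270-fold and 1540-fold (8.04 ± 1.14 and 10.56 ± 1.69, adjusted p = 0.000301 and 0.000611). Cdkn1a rose 33.2-fold to 433.6 ± 311 CPM (5.06 ± 0.649, adjusted p = 0.000158). Hba-a2 fell 651-fold (-9.34 ± 1.08, adjusted p = 7.97e-05), and Slc22a2, the transporter that carries cisplatin into tubule cells, was at 101.8 ± 40.7 CPM against 77.79 ± 23.8 (0.39 ± 0.297, adjusted p = 0.322).

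Of 24 p53 target genes in kidney 20 rose (23 adjusted over the list alone; median 1.83; camera adjusted p = 1.9e-08, and adjusted p = 0.275 with an estimated correlation), including the stress cytokine gene Gdf15, 89-fold, and Btg2, 48-fold (adjusted p = 0.000522 and 0.000574). Acute-phase genes rose in 18 of 26 cases (18 adjusted over the list alone; median 4.20, or 3.77 with genes absent from a group at their bound; camera adjusted p = 1.81e-05, and adjusted p = 0.275 with an estimated correlation). Saa1 rose 876-fold and the fibrinogen gene Fgg 642-fold (adjusted p = 0.000308 and 0.00026). NRF2 and antioxidant genes rose in 16 of 24 (17 adjusted over the list alone; median 1.61; camera adjusted p = 1.81e-05, and adjusted p = 0.275 with an estimated correlation). Mt1 also rose 57.7-fold and Mt2 81.1-fold (adjusted p = 0.000662 and 0.000478). Tubular injury genes rose in 14 of 23 cases and 3 fell, also adjusted over the list alone (median 3.4; camera adjusted p = 0.0125, and adjusted p = 0.496 with an estimated correlation), with the overlapped gene Spp1 50-fold higher (adjusted p = 0.000157). Fatty acid oxidation genes rose in 20 of 25 (20 adjusted over the list alone; median 1.62; camera adjusted p = 1.57e-09, and adjusted p = 0.0807 with an estimated correlation). Cyp4a14 rose 146-fold and the kinase gene Pdk4 26.9-fold (adjusted p = 8.13e-06 and 0.00102). NF-kB and chemokine genes had 14 of 26 higher and 3 lower (median 1.08, camera adjusted p = 0.102), with the neutrophil chemokine gene Cxcl1 533-fold and Tnfrsf12a 122-fold higher (adjusted p = 0.000452 and 0.000219). Without cisplatin 6 this list was called.

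Stromal, endothelial, lymphocyte and erythroid genes fell in kidney after cisplatin. Stromal genes fell in 12 of 15 cases (13 adjusted over the list alone; median -3.28; camera adjusted p = 1e-09, and adjusted p = 0.0807 with an estimated correlation). The collagen gene Col3a1 fell 39.5-fold and the smooth muscle myosin gene Myh11 37.7-fold (adjusted p = 0.000625 and 4.95e-05). Endothelial genes fell in 9 of 14 (10 adjusted over the list alone; median -2.56; camera adjusted p = 1.22e-05), among them the cadherin gene Cdh5, 10.4-fold (adjusted p = 0.000939). Lymphocyte genes fell in 12 of 18 (12 adjusted over the list alone; median -3.45; camera adjusted p = 9.99e-05). Both had adjusted p = 0.275 with an estimated correlation. Erythroid genes fell in 5 of 6 (5 adjusted over the list alone; median -7.90; camera adjusted p = 1.81e-05, and adjusted p = 0.0807 with an estimated correlation), with Hbb-bt, Hba-a1 and Hbb-bs 293-fold, 255-fold and 219-fold lower (adjusted p = 0.000183, 0.000155 and 0.000366). Adipose genes were lower in 3 of 8 (3 adjusted over the list alone; median -3.69; camera adjusted p = 0.149, or 0.000623 without control 2). Cholangiocyte genes, Spp1 among them, rose in 6 of 10 and 1 fell, also adjusted over the list alone (median 1.80; camera adjusted p = 0.0166, or 0.057 without control 1, and adjusted p = 0.275 with an estimated correlation). Neutrophil genes had 1 of 8 higher and 1 lower, or 0 adjusted over the list alone (median 1.23, camera adjusted p = 0.943). Podocyte genes fell in 6 of 12 cases and 1 rose, or 7 and 1 adjusted over the list alone (median -1.11, camera adjusted p = 0.0534). The podocyte transcription factor gene Wt1 fell 3.13-fold (-1.63, adjusted p = 0.0393), and the proliferation gene Mki67 fell 11-fold (-3.44 ± 0.612, adjusted p = 0.00116). Proximal tubule genes had 9 of 25 higher and 1 lower (median 0.37, camera adjusted p = 0.0636).

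Also higher were Sprr2g, a squamous envelope gene, at least 553-fold (adjusted p = 0.00447), the AP-1 gene Fosl1, at least 254-fold (adjusted p = 0.0169), and the cytochrome gene Cyp2b10, at least 235-fold (adjusted p = 0.0127). Septin2, Ugt1a10 and Adnp were higher as well, by at least 905-fold, at least 433-fold and 1210-fold (adjusted p = 0.0256, 0.000393 and 0.00162), but overlap other genes or stand on several IDs and are uncertain. The small RNA gene Rn7s6 and the transfer RNA gene mt-Tg fell 219-fold and 204-fold (adjusted p = 3.34e-05 and 7.71e-05), the former with near-identical copies. Not called were Mdm2 (0.80 ± 0.328, adjusted p = 0.0716), Alb (1.98 ± 0.784, adjusted p = 0.0642) and Tlr5 (adjusted p = 0.338).

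In total 7999 of 20341 kidney genes were called, 4900 higher and 3099 lower, and 9891 had an unadjusted p under 0.05. Median-of-ratios scaling gave 4260 and 3673, and log2(FPKM + 1) 10737 and 171. Mdm2 was called without cisplatin 6 (adjusted p = 0.000271) and Alb without control 2 or 3 (0.0459 and 0.0233). The Wt1 call ended without control 1 or 2 (0.138 and 0.0524) or cisplatin 4 or 5 (0.107 and 0.112), and the Septin2 call without control 1, 2 or 3 (0.0581, 0.0643 and 0.0639) or cisplatin 5 (0.0555). Under limma-voom Havcr1 had an adjusted p of 0.145, Krt20 0.316, Saa1 0.165, Cxcl1 0.247, Gdf15 0.0587, Sprr2g 0.444, Fosl1 0.518 and Cyp2b10 0.455.

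CBLB502 against control in kidney showed part of the nephron genes higher. Umod, the most abundant urinary protein gene of the thick limb, rose 6.44-fold (2.69 ± 0.404, adjusted p = 0.00112), and Slc12a3, the thiazide-sensitive salt transporter, 3.35-fold to 725.7 ± 93.5 CPM (1.74 ± 0.247, adjusted p = 0.000797). The smooth muscle genes Acta2 and Myh11 fell 6.73-fold and 9.2-fold (-2.75 ± 0.289 and -3.20, adjusted p = 0.000132 and 0.00143). Havcr1 was at 0.7802 ± 0.157 CPM and 1.266 ± 0.387 in control (-0.66 ± 0.934, adjusted p = 0.677).

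Of 25 proximal tubule genes 12 rose (16 adjusted over the list alone; median 1.28; camera adjusted p = 2.48e-07, and adjusted p = 0.436 with an estimated correlation). The cystine transporter gene Slc3a1 rose 6.02-fold and the water channel gene Aqp1 4.82-fold (adjusted p = 0.000173 and 0.00149). Distal nephron genes rose in 9 of 22 cases and 1 fell (11 and 1 adjusted over the list alone; median 1.10; camera adjusted p = 0.000584). Podocyte genes rose in 4 of 12 (4 adjusted over the list alone; median 0.87; camera adjusted p = 0.0119). Both had adjusted p = 0.549 with an estimated correlation. Platinum transport and binding genes rose in 7 of 18 (10 adjusted over the list alone; median 0.88; camera adjusted p = 3.14e-05, and adjusted p = 0.0186 with an estimated correlation). Xenobiotic cytochrome P450 genes rose in 8 of 19 (8 adjusted over the list alone; median 1.66, or 1.63 with genes absent from a group at their bound; camera adjusted p = 3.14e-05, and 0.0186). Fatty acid oxidation genes rose in 13 of 25 (16 adjusted over the list alone; median 0.66; camera adjusted p = 3.98e-06, and adjusted p = 0.344 with an estimated correlation), with Cyp4a14 17.8-fold higher (4.13 ± 0.481, adjusted p = 0.000253). Stromal genes fell in 6 of 15 (9 adjusted over the list alone; median -1.77; camera adjusted p = 4.75e-06, and adjusted p = 0.436 with an estimated correlation). Adrenal cortex genes were lower in 2 of 5 cases (2 adjusted over the list alone; median -2.37; camera adjusted p = 0.0657, or 0.00692 without control 3), and adipose genes in 0 of 8 (median -3.47, camera adjusted p = 0.0888, or 2.81e-05 without control 2). In the combination against CBLB502 these medians were -0.30 and -0.05. Tubular injury genes fell in 7 of 23 and 1 rose, also adjusted over the list alone (median -0.66; camera adjusted p = 0.0384, and adjusted p = 0.737 with an estimated correlation). The keratin gene Krt19 fell 5.22-fold (-2.38, adjusted p = 0.0237). The squamous gene Sprr1a and the stress gene Nupr1 fell 15.1-fold and 4.95-fold (adjusted p = 0.00501 and 0.000347).

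Another gene higher with CBLB502 in kidney was Dbp, 8.03-fold (adjusted p = 7.17e-05). The glycosyltransferase gene B3gnt2, Scamp4, Adnp, Ugt1a10 and Nnt were 13.9-fold, 12.5-fold, 1820-fold, at least 280-fold and at least 604-fold higher (adjusted p = 0.0201, 0.00679, 0.00283, 0.00152 and 0.00142). They overlap other genes or stand on several IDs and are uncertain, and Nnt had no count in the other groups. Lower were mt-Nd2, mt-Td and mt-Ts1, 36.7-fold, 119-fold and 39.6-fold (adjusted p = 3.44e-05, 4.19e-05 and 2.93e-05), and the small RNA genes Rn7s6, Rn7s2 and Rn7s1, 1500-fold, 62-fold and 50.5-fold (adjusted p = 4.43e-05, 0.00141 and 0.00176), which are near-identical copies. Not called were Cdkn1a (-1.74 ± 0.571, adjusted p = 0.0529), Slc22a2 (0.89 ± 0.299, adjusted p = 0.0583), Lcn2 (adjusted p = 0.695), Saa1 (adjusted p = 0.743), Mdm2 (adjusted p = 0.871), Alb (adjusted p = 0.119) and Tlr5 (adjusted p = 0.518).

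In total 3904 kidney genes were called for CBLB502, 2324 higher and 1580 lower (6667 at an unadjusted p under 0.05), and 2372, 2290 or 2597 without CBLB502 4, 5 or 6. The B3gnt2 call ended without control 1 or 3 or CBLB502 5 (adjusted p = 0.0724, 0.0762 and 0.0651) and under limma-voom (0.37), and the Krt19 call without control 1 or 3 or CBLB502 4 (0.0549, 0.061 and 0.0844). Slc22a2 was called without control 2 (0.0353) and Alb without control 3 (0.0499), mt-Nd2 was not called after quantile normalization (0.313), and median-of-ratios scaling called Cdkn1a (0.0479). The tubular injury list lost its call without control 1 or CBLB502 6, and the podocyte list without control 2.

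The combination against cisplatin in kidney called a single gene. Noct (ENSMUSG00000023087, chromosome 3, 51224447 to 51251644), which encodes the circadian phosphatase nocturnin and overlaps a predicted gene, was 4.31-fold higher at 113.8 ± 30.9 CPM against 26.38 ± 2.08 (2.11 ± 0.2, adjusted p = 0.00486). Havcr1 was at 3.993 ± 0.748 CPM against 162.2 ± 144 without passing the test (-5.34 ± 0.916, adjusted p = 0.223). Lcn2 was at 121.1 ± 34.5 against 814.5 ± 669 (-2.75 ± 0.885, adjusted p = 0.259) and Cdkn1a at 195.5 ± 23 against 433.6 ± 311 (-1.15 ± 0.55, adjusted p = 0.407). Havcr1 was at 294.1, 184.4 and 8.25 CPM in libraries 4, 5 and 6 and at 3.148 to 4.569 in the combination, and Cdkn1a at 626.4, 600.2 and 74.26 against 180.6 to 222.

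No member of the following kidney lists was called over all genes. NF-kB and chemokine genes had 13 of 26 lower adjusted over the list alone (median -1.31, camera adjusted p = 1.73e-10) and acute-phase genes 7 of 26 (median -1.84, camera adjusted p = 3.73e-09). Tubular injury genes had 10 of 23 (median -1.08, camera adjusted p = 9.47e-07) and neutrophil genes 2 of 8 (median -2.55, camera adjusted p = 0.000847). Fatty acid oxidation genes had 5 of 25 higher adjusted over the list alone (median 0.37, camera adjusted p = 2.11e-05). For these lists the estimated correlation gave adjusted p = 0.423. Proximal tubule genes (median 0.38, camera adjusted p = 0.000269) and p53 target genes (median -0.47, camera adjusted p = 0.0228) had adjusted p = 0.694 with an estimated correlation. The p53 list lost its call without cisplatin 4 or 5 or combination 5 or 6, the proximal tubule list without cisplatin 5, and the fatty acid oxidation list without cisplatin 6.

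Beside the single call, 2614 kidney genes had an unadjusted p under 0.05, DESeq2 called 623 genes and limma-voom 6, and limma-voom with library weights 4042. Without cisplatin 6 the count was 4714, with Havcr1, Lcn2, Cdkn1a, Saa1 and Mdm2 called lower (adjusted p = 1.29e-06, 0.000362, 0.00025, 0.000954 and 0.00617). Without cisplatin 4 or 5 it was 0 and Noct had an adjusted p of 0.0666 or 0.0579, and without combination 4 or 6 it was 2. Not called in the full set were Saa1 (-3.01 ± 0.928, adjusted p = 0.253), Slc22a2 (0.34, adjusted p = 0.693), Mdm2 (-0.49, adjusted p = 0.569), Alb (-0.20, adjusted p = 0.956) and Tlr5 (-1.96, adjusted p = 0.618).

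Against CBLB502 alone, the combination in kidney showed most p53 targets higher and haemoglobin genes and Slc12a3 lower. Cdkn1a rose 50.2-fold from 3.892 ± 0.726 to 195.5 ± 23 CPM (5.65 ± 0.665, adjusted p = 0.000268), and Lcn2 rose 59.3-fold (5.89 ± 1.03, adjusted p = 0.00202). Hba-a2 fell 899-fold from 108.2 ± 66.4 CPM (-9.79 ± 1.12, adjusted p = 0.000227). Slc12a3 fell 11.5-fold from 725.7 ± 93.5 to 62.93 ± 15.5 CPM (-3.53 ± 0.265, adjusted p = 5.53e-05). Havcr1 was 5.12-fold higher without passing the test (2.35 ± 0.833, adjusted p = 0.061).

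Of 24 p53 target genes 18 rose and 1 fell (21 and 1 adjusted over the list alone; median 1.86; camera adjusted p = 7.09e-14, and adjusted p = 0.244 with an estimated correlation). The p53 targets Psrc1 and Phlda3 rose 23.3-fold and 13.9-fold (adjusted p = 0.000168 and 0.00159). Tubular injury genes rose in 13 of 23 cases and 1 fell (16 and 1 adjusted over the list alone; median 1.88; camera adjusted p = 8.01e-05, and adjusted p = 0.392 with an estimated correlation), and Krt20 rose 29.8-fold (4.89 ± 1.32, adjusted p = 0.02). Podocyte genes fell in 7 of 12 (9 fell and 1 rose adjusted over the list alone; median -1.79; camera adjusted p = 9.01e-06, and adjusted p = 0.379 with an estimated correlation), including Wt1, 6.18-fold (adjusted p = 0.00691). Distal nephron genes had 4 of 22 lower and 2 higher (median -0.53; camera adjusted p = 0.0122, and adjusted p = 0.567 with an estimated correlation), among them the calcium-binding gene Pvalb, 14.2-fold lower (adjusted p = 0.00102). Fatty acid oxidation genes rose in 15 of 25 and 1 fell (18 and 1 adjusted over the list alone; median 1.03; camera adjusted p = 4.3e-09, and adjusted p = 0.137 with an estimated correlation), with Cyp4a14 14.7-fold higher (adjusted p = 0.000286). Erythroid genes fell in 5 of 6 (5 adjusted over the list alone; median -6.62; camera adjusted p = 1.03e-06, and adjusted p = 0.137 with an estimated correlation), Hbb-bt, Hba-a1 and Hbb-bs by 125-fold, 106-fold and 92.4-fold (adjusted p = 0.000693, 0.000683 and 0.00146). Macrophage genes fell in 5 of 16 (8 adjusted over the list alone; median -2.10; camera adjusted p = 0.00074, and adjusted p = 0.392 with an estimated correlation), with the monocyte receptor gene Ccr2 31.3-fold lower (adjusted p = 0.00547).

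Also called were Saa1, 201-fold higher (7.64 ± 1.23, adjusted p = 0.00128), Cxcl1, 53.9-fold, Tnfrsf12a, 10.9-fold, and Mt2, 11.9-fold (adjusted p = 0.00393, 0.00851 and 0.0108), and Gpx4, which reduces lipid peroxides, 5.17-fold (2.37 ± 0.223, adjusted p = 0.000133). Ly6f was 77.6-fold higher (adjusted p = 0.000524), Sprr2g 86.5-fold (adjusted p = 0.0193), and the histone gene H2ac18, which overlaps a predicted gene, at least 1290-fold (adjusted p = 0.0253). Col3a1 and the endothelial receptor gene Kdr fell 13.3-fold and 9.87-fold (adjusted p = 0.0059 and 0.0128), and the uncertain Nnt at least 3240-fold (adjusted p = 0.000614). Not called were Mdm2 (adjusted p = 0.682), Slc22a2 (adjusted p = 0.741) and Alb (adjusted p = 0.954).

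In total 4848 genes were called for this comparison, 3021 higher and 1827 lower (7387 at an unadjusted p under 0.05). The majority turned on log2(FPKM + 1) (1736 and 2620) and with only these groups in the fit (4589 and 4843), and the changes had a rank correlation of -0.374 with transcript length. The count was 2823 without CBLB502 4, 2823 without CBLB502 5, 3144 without combination 5 and 3137 without combination 6. Calls ended for Krt20 without CBLB502 4, 5 or 6 (adjusted p = 0.0725, 0.0611 and 0.0709), and for Sprr2g without CBLB502 5 or 6 (0.0741 and 0.0638). They also ended for H2ac18 without any CBLB502 library (0.075, 0.0743 and 0.0638) or combination 4 (0.0622), for Mt2 without CBLB502 5 (0.0527) and for Kdr without combination 4 or 6 (0.0566 and 0.0511). Under limma-voom Saa1 had an adjusted p of 0.107, Cxcl1 0.153, Krt20 0.434 and Sprr2g 0.414.

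**Figure D4:**
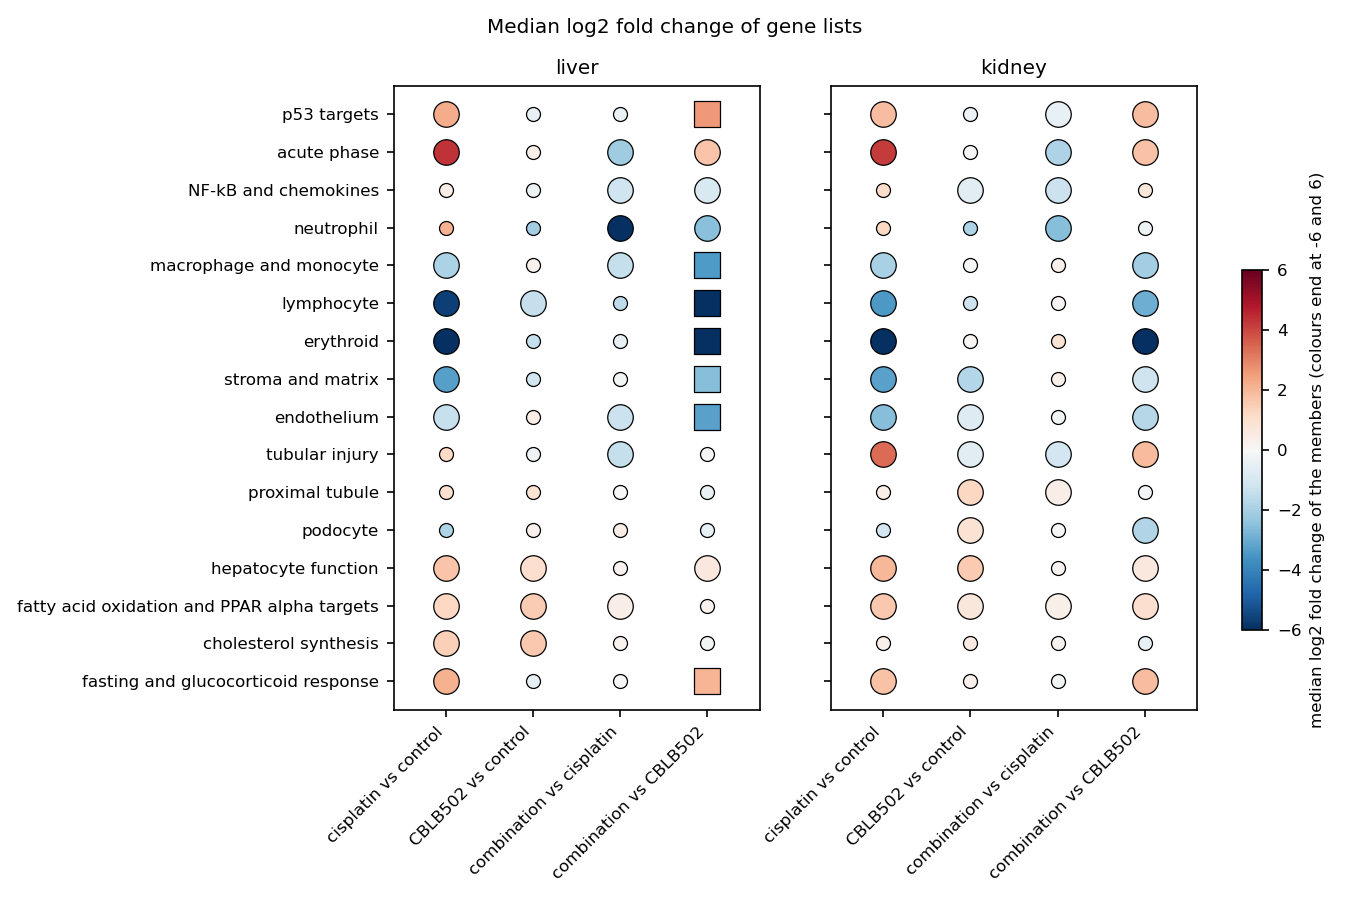
Median log2 fold change of the members of 16 gene lists (colour) in 4 comparisons of liver and kidney. Large markers have a camera adjusted p under 0.05 with the preset correlation, and squares keep it with an estimated correlation.

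The kidney changes of cisplatin against control and of the combination against CBLB502 had a Pearson r of 0.36 and a Spearman rho of 0.48 across genes (covariance 1.28). Both called 2181 genes higher, where independent lists would share 727.7, and 908 lower, where they would share 278.3, and 124 went opposite ways. The combination against control called 7429 genes, 4369 higher and 3060 lower (9383 at an unadjusted p under 0.05), or 3634 higher and 3669 lower with median-of-ratios scaling. A ratio of 1.02 (0.881 to 1.29 over 9 choices) of the kidney cisplatin effect remained in the combination for genes that rose and 1.06 (0.781 to 1.51) for genes that fell. By held-out cisplatin library 4, 5 and 6 the ratio was 0.887, 0.889 and 1.28 for genes that rose and 0.81, 0.91 and 1.46 for genes that fell, or 0.833, 0.744 and 1.58, and 0.813, 0.792 and 2.02, with CBLB502 libraries in place of control.

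The kidney interaction named genes whose cisplatin change differed with CBLB502. The fibrinogen gene Fgb (-5.94 ± 1.53, adjusted p = 0.0367) and the protein Z-dependent protease inhibitor gene Serpina10 (-5.18 ± 1.32, adjusted p = 0.0353) had a smaller cisplatin increase with CBLB502. Fgb was at 526.3 ± 453 CPM after cisplatin and 24.08 ± 6.53 after the combination. Rn7s6, mt-Td, Rn7s2, Rn7s1 and mt-Ts1, which were highest in the controls, had positive values (10.26 ± 1.16, 7.59 ± 0.777, 5.88, 5.57 and 5.25; adjusted p = 0.000791, 0.000487, 0.0126, 0.0156 and 0.000501). Stromal genes were higher in 4 of 15 cases (7 adjusted over the list alone; median 1.91; camera adjusted p = 2.25e-07, and adjusted p = 0.439 with an estimated correlation). Platinum transport genes were lower in 5 of 18 (7 adjusted over the list alone; median -1.36; camera adjusted p = 0.00119, and adjusted p = 0.0638 with an estimated correlation).

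In total 1629 genes were called in the kidney interaction, 528 higher and 1101 lower (5124 at an unadjusted p under 0.05), or 98 and 10775 on log2(FPKM + 1). The count was 5333 without cisplatin 6, 1005 without cisplatin 4, 936 without control 3, 677, 744 or 1011 without CBLB502 4, 5 or 6, and 836, 703 or 751 without combination 4, 5 or 6. Fgb lost its call without any library but control 2 and cisplatin 6 (adjusted p = 0.051 to 0.0961), and Serpina10 without any but control 1 and cisplatin 5 and 6 (0.0665 to 0.0878). Under limma-voom Fgb had an adjusted p of 0.29 and Serpina10 0.412.

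The difference between the tissues was tested as kidney minus liver change. For cisplatin, Lepr rose in liver (log2 fold change 8.90) and not in kidney (-1.73), a difference of -10.62 ± 1.93 (adjusted p = 0.00134). Tfr2, a sensor of iron supply, and the amyloid gene Saa4 had no count in control kidney and 2.09 and 1.994 CPM after cisplatin, and log2 fold changes of 0.70 and 0.74 in liver (adjusted p = 0.000328 and 0.00277). Atp4a, a gastric proton pump subunit, had 2.555 CPM in control liver, no count after cisplatin, and a log2 fold change of 0.85 in kidney (adjusted p = 9.54e-05). In total 3062 of 21570 genes differed, 1672 more positive in kidney and 1390 in liver (6032 at an unadjusted p under 0.05), and 235 were called in both tissues with opposite signs. The majority turned with quantile normalization (1376 and 1599) and without kidney cisplatin 6 (1762 and 1815).

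For the combination against cisplatin, the coagulation initiator gene F3 had -3.28 in kidney and 1.43 in liver (difference -4.70 ± 0.911, adjusted p = 0.0184). The membrane protein gene Cdcp1 had -1.19 and 1.75 (-2.94 ± 0.618, adjusted p = 0.0265) and the anchoring gene Lad1 -0.18 and 2.85 (-3.03 ± 0.66, adjusted p = 0.0325). The glycosyltransferase gene B4galnt3, with no count in liver cisplatin libraries, and Rpph1, with none in liver combination libraries, differed too (adjusted p = 0.0184 each). In total 208 genes differed, 144 more positive in kidney and 64 in liver (2950 at an unadjusted p under 0.05). The count was 1632 without liver cisplatin 3, 744 without kidney cisplatin 6, 88 or 83 without liver cisplatin 1 or 2, and 7 without kidney cisplatin 4. It was 80, 80 or 7 without liver combination 1, 2 or 3, and 7, 0 or 60 without kidney combination 4, 5 or 6. Each of these 5 genes lost its call without liver combination 3 (adjusted p = 0.0516 to 0.0589), kidney cisplatin 4 (0.0662 to 0.0855), kidney combination 4 (0.0549 to 0.0711) or kidney combination 5 (0.058 to 0.0957).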

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

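The tests of few genes taking the counts, of the cisplatin libraries that stood apart, of the spread within splits and of the fall in erythroid and lymphocyte transcripts were chosen after these results were seen.

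Tests of the difference between effects gave 4 results. The interaction called 3885 liver and 1629 kidney genes, but includes the controls, whose difference stays open as a cause. Among 30 splits of the libraries, the real one included, the highest other gave 1 gene in liver and 3 in kidney. The others mix treated with control libraries, which raised the dispersion within groups to at least 1.91 and 2.1 times the real one, so they do not decide whether chance can be excluded. Kidney and liver differed in the cisplatin effect in 3062 genes and in the effect of the combination against cisplatin in 208. In each case 3 of 25 splits gave as many, the real one included. For cisplatin the other 2, with 5392 and 4387 genes, kept the liver or the kidney groups whole and so hold a treatment effect, which points to a structure of the samples. The highest with neither kept whole gave 962, and the splits do not decide whether chance can be excluded. For the combination against cisplatin the others gave 1795, with the liver groups whole, and 450, with neither whole, so chance cannot be excluded.

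With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In liver the real and the highest other counts were 7727 and 55 for cisplatin against control, 4984 and 0 for CBLB502 against control, 640 and 1 for the combination against cisplatin, 7203 and 0 for the combination against control, and 1209 and 0 for the combination against CBLB502. In kidney they were 7999 and 30, 3904 and 0, 1 and 23, 7429 and 0, and 4848 and 0 in the same order. For the kidney combination against cisplatin 2 of 10 splits gave as many, and the split with 23 points to a structure of the samples.

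The control libraries of both tissues stood apart in mitochondrial share. That a few genes took most of the counts stays open as a cause of changes against control. Leaving them out kept 97.3% of the liver genes and 97.9% of the kidney genes called for cisplatin, but TMM scaling trims such genes already. On log2(FPKM + 1), without that scaling, 98.6% and 98.4% of the called genes were higher, as such genes could produce. A different alignment or counting of the controls would change the counts on chromosome 1 copies per mitochondrial count, and the ratio of controls to treated libraries was 0.942 in liver and 0.983 in kidney, which argues against it. A gene length bias of the control RNA cannot be told apart from treatment, since the rank correlation of the CBLB502 change with transcript length was -0.0337 in liver and 0.217 in kidney. It was larger in size for the combination against CBLB502 (-0.0821 and -0.374), which uses no control. That treatment itself lowered mitochondrial transcripts stays open, because no other untreated libraries were analysed.

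Liver cisplatin library 3 and kidney cisplatin library 6 stood apart from their groups. A swap with a combination library needs a partner nearer to the other cisplatin libraries than to its own group, and 0 combination libraries in the 2 tissues were. Lower depth is argued against by their counts outside mitochondrial genes and copies, 0.993 and 1.04 times the lowest other cisplatin library. A combination library under a cisplatin label would change as that group does on genes called for the other cisplatin libraries. Kidney library 6 had 0.799 of the group's mean change on genes that rose and 0.72 on genes that fell, outside the 95% prediction intervals (0.962 to 1.04 and 0.775 to 1.23), which argues against it there. Liver library 3 had 0.989 and 0.886, inside them (0.903 to 1.1 and 0.801 to 1.2). The smallest distance to a pair of combination libraries was 1.51 times the largest within that group in liver, which counts against it. The kidney value, 1.06, does not. The liver tests disagree, so there it cannot be told apart from a weak response. A weak response was not tested.

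Erythroid and lymphocyte transcripts fell after cisplatin in both tissues. Erythroid genes argue against a difference of the control libraries alone, as 5 fell in each tissue for the combination against CBLB502, whose contrast uses no control. Less blood in the tissue would lower neutrophil and erythroid genes alike, but the neutrophil median was above the erythroid median by 5.67 in liver and 6.32 in kidney on the log2 scale. Neutrophils entering the tissue could hide a loss of blood in part. No biological explanation was tested.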

How the results depend on the processing

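The tests with DESeq2, limma-voom without weights, limma on log2(FPKM + 1), fits without control libraries, fits without mitochondrial genes, the block on column numbers, CBLB502 libraries in place of control, and all tests of the combination against CBLB502 were chosen after the data were seen, and the others before.

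Over 3941 values of named genes under an alternative, 3531 kept their direction and their side of the threshold, 342 lost the call, 62 gained it and 6 reversed. Over 758 values of lists 670 kept their side, 75 lost the call and 13 gained it. Over 309 values of counts, correlations and remaining effects 206 stayed the same, 59 were lower, 33 higher and 11 moved by more than the spread. Except where a value below shows it, the cause was not tested.

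With median-of-ratios scaling, and without mitochondrial genes and their copies, every count stayed within 1.5 times. Quantile normalization gave 365 genes for the liver combination against cisplatin and 48 for its difference between tissues. No filter gave 390 and 117 for these, and correlations of the cisplatin effect with and without CBLB502 of 0.242 in liver and 0.175 in kidney. A filter of at least 5 FPKM in 3 libraries tests fewer genes. It gave 2605 liver genes for cisplatin, 1917 for CBLB502 and 2249 for the combination against control, 1619 for the interaction and 396 for the combination against CBLB502. In kidney it gave 3590, 2258 and 3455 against control and 3025 for the combination against CBLB502, with a correlation of 0.61, and 355 genes for the tissue difference of the combination against cisplatin.

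With only the groups of the contrast in the fit, fewer libraries estimate the spread. The counts were 4240 in liver and 4215 in kidney for cisplatin against control, 54 and 0 for the combination against cisplatin, and 5329 and 9432 for the combination against CBLB502. The tissue differences were 279 for cisplatin and 2 for the combination against cisplatin. Without control libraries edgeR gave 1471 liver genes and 0 kidney genes for the combination against cisplatin.

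Limma-voom with library weights gave 7457, 5917 and 6248 liver genes for the combination against cisplatin, the interaction and the combination against CBLB502. In kidney it gave 4042, 5286 and 11320 for these and 6927 for CBLB502 against control, and 3970 for the tissue difference of the combination against cisplatin. Limma-voom without weights gave 1943 and 2805 liver genes for the combination against cisplatin and against CBLB502, and 6 in kidney for the combination against cisplatin. DESeq2 gave 2540 and 2604 in liver, and 623 for the kidney combination against cisplatin and 3081 for the kidney interaction. Limma on log2(FPKM + 1) gave 9818 liver genes for CBLB502 against control, 2804 for the combination against cisplatin and 8782 for the interaction. In kidney it gave 11826 for CBLB502 and 11315 for the combination against control, 13 for the combination against cisplatin and 10873 for the interaction. Against control nearly all its calls were higher, 99.4% and 99.2% for CBLB502 in liver and kidney.

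The replicate block gave 390 genes for the liver combination against cisplatin, and a block by column number without control libraries gave 0 for kidney. No set of libraries paired by number had every same-number correlation above 0.1 (liver -0.169 to 0.176, treated kidney -0.133 to 0.0705). With CBLB502 libraries in place of control, 0.701 of the liver increase and 1.1 of the liver decrease remained, against 0.924 and 0.932, and in kidney 1.05 and 1.21, against 1.02 and 1.06. By cisplatin library they ran from 0.563 to 1.55 in liver and from 0.744 to 2.02 in kidney.

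Reversed values were Mdm2 in liver after cisplatin with the 5 FPKM filter (-0.04778, adjusted p = 0.898) and Cyp7a1 in liver after cisplatin without cisplatin 3 (-3.689, adjusted p = 0.00984, and up to 2.412 without cisplatin 2). With limma on log2(FPKM + 1) they were Mdm2 (1.674) and Cdkn1a (0.7444) in liver after CBLB502, Wt1 in kidney after cisplatin (0.05838) and Nupr1 in kidney after CBLB502 (0.005053).

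With each library left out in turn, liver counts ran from 6425 to 8699 for cisplatin against control, 3510 to 5208 for CBLB502, 5618 to 6961 for the combination against control and 2735 to 5694 for the interaction. They ran from 7 (without combination 2) to 4344 (without cisplatin 3) for the combination against cisplatin, and from 478 (without CBLB502 1) to 599 (without CBLB502 3) for the combination against CBLB502. Kidney counts ran from 6374 to 10756 for cisplatin, 2290 (without CBLB502 5) to 3463 for CBLB502 and 5652 to 6837 for the combination against control. They ran from 0 (without cisplatin 4 or 5) to 4714 (without cisplatin 6) for the combination against cisplatin, 677 (without CBLB502 4) to 5333 (without cisplatin 6) for the interaction, and 2823 (without CBLB502 4 or 5) to 3787 for the combination against CBLB502. Correlations ran from 0.304 to 0.436 in liver and 0.311 to 0.433 in kidney. The tissue differences ran from 2375 to 4317 for cisplatin, and from 0 (without kidney combination 5) to 1632 (without liver cisplatin 3) for the combination against cisplatin.

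The replicate block planned for kidney and for the tissue difference was not run, because treated kidney columns are numbered 4 to 6, and a pseudocount of 0.1 applied only to the remaining effect because counts were tested. Control libraries held fewer counts outside mitochondrial genes than treated ones, which limits low-count genes there.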

Other observations

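The comparisons of the combination with CBLB502, and the choice of the lists and genes given here, were made after the results were seen, and the values have no explanation attached.

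In liver, interferon response genes were lower in the combination than in CBLB502 in 8 of 27 cases (19 adjusted over the list alone; median -1.95; camera adjusted p = 3.32e-12, and adjusted p = 0.178 with an estimated correlation). Fatty acid synthesis genes were lower in 7 of 18 cases (11 adjusted over the list alone; median -1.08; camera adjusted p = 1.14e-10, and adjusted p = 0.0861 with an estimated correlation), with the regulator gene Srebf1 at 26.85 ± 6.47 CPM against 148.4 ± 5.34 (-2.47 ± 0.435, adjusted p = 0.00695).

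In kidney, the adrenal cortex list had 3 of 5 genes lower with cisplatin (4 adjusted over the list alone; median -5.03; camera adjusted p = 0.047, and adjusted p = 0.275 with an estimated correlation), a call that ended without control 1 (0.122) or cisplatin 6 (0.149) and with median-of-ratios scaling (0.0537). It had 2 of 5 lower with CBLB502 (2 adjusted over the list alone; median -2.37; camera adjusted p = 0.0657) and 4 of 5 with the combination (4 adjusted over the list alone; median -2.68; camera adjusted p = 0.0558). In the combination against CBLB502 it had 0 of 5 (median -0.30).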
